A study of Solanum lycopersicum with 4 samples.

How the data were processed

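Small RNA was sequenced from leaves of the tomato (Solanum lycopersicum) cultivar Pusa Ruby, in 2 mock-inoculated and 2 infected libraries. Per the labels, infected leaves received drops of about 10 microlitres of a suspension of the leaf-blight fungus Alternaria at about 1000000 colony forming units per ml. Mock leaves received the buffer alone, and tissue was collected about 72 h later. Of the infected leaves only the infection zone was taken. The libraries were made with the Illumina TruSeq Small RNA kit, per the labels' protocols. RNA of mock 1, mock 2 and infected 1 was extracted with Trizol and RNA of infected 2 with an Agilent plant RNA kit, so the kit separates the 2 infected libraries from each other. The labels do not say whether libraries of a group came from separate plants. The p-values therefore measure only the spread between these libraries, which may be technical.

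The authors deposited, for each library, a list of unique read sequences with the raw read count of each. The submitters' processing notes name cutadapt, which removes adapters, and DESeq, with no version for either. An aligner, a genome build and a miRNA catalogue are not given in the sources used here. The lists hold sequences of 18 to 25 nt. Mock 1 lists 65535 sequences and 2559750 reads, mock 2 lists 1163133 sequences and 5092406 reads, infected 1 lists 636784 sequences and 3376247 reads, and infected 2 lists 218018 sequences and 1509619 reads. The file of mock 1 ends at line 65536, and its lowest count is 4, whereas the others go down to a count of 1. A sequence missing from mock 1 can therefore have had up to 4 reads, the total of mock 1 is that of its listed sequences, and its values per 1000000 reads (RPM) are higher than they would be over the whole library. No floor from a count of 0 was used for mock 1.

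A reference of 46 miRNA entries (73 mature sequences) and 6 lists of them (development, auxin, silencing, copper, nutrient and immune receptor) was written from general knowledge before the data were examined. A miRNA's count was the sum of the reads that matched a reference sequence without mismatch and whose ends lay within 2 nt of its ends. No read matched 2 entries equally well (0 reads). A gene table of the tomato assembly SLM_r2.1 names miRNA genes for 37 of the 46 entries. It was used for names alone, and positions in the genome were not analysed here. Members of one family with near-identical mature sequences, such as miR165 and miR166, were counted as one entry, named miR166 here, and reads of loci that give the same mature sequence cannot be separated. Fungal rRNA was measured as the reads of 18 nt or more that match exactly the short rRNA that pairs with the large-subunit rRNA of Alternaria and do not occur in the plant sequence of that rRNA. Both sequences were written from general knowledge, and since this rRNA is conserved they do not separate Alternaria from related fungi. Chloroplast 4.5S rRNA fragments were counted the same way on a sequence of 103 nt chosen after the data were seen.

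Counts per known miRNA and counts per unique sequence were each tested with edgeR 4.0.16 in R 4.3.3, by glmQLFit and glmQLFTest on the deposited counts, with TMM scaling, the filterByExpr defaults and infection status as the only term. p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Standard errors of log2 fold changes were computed from the F statistic. The lists were tested with camera of limma 3.58.1 (preset correlation 0.01, log-CPM with a prior count of 2), beside camera with an estimated correlation and fry. Shares of reads were compared by a two-sided exact permutation test, which for 2 against 2 libraries cannot go below 0.333. Values are means ± SD with n = 2 libraries per group. The 95% Wilson intervals of the length and miRNA shares of single libraries are at most ± 0.0636 percentage points wide. They cover counting error only, since PCR copies were not separated. RPM values are reads per 1000000 listed reads of a library. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 did the counting and the plots.

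On simulated counts with the observed spread (biological coefficient of variation 0.651), edgeR recovered 12 of 81 unique sequences changed 32-fold and 0 of 79 changed 4-fold, among 22513 tested, with 0 false calls. DESeq2 1.42.0 recovered 56 of 81 and 2 of 79, with 10 false calls. For known miRNAs (31 tested, coefficient 0.673) edgeR recovered 3 of 4 changed 32-fold and 0 of 4 changed 4-fold.

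The text names, by a rule fixed before the data were examined, the list members that pass the test and up to 4 others per list by highest mean, the 5 most abundant known miRNAs, and unique sequences that pass, or else the 5 with the smallest p in each direction. Sequences that are higher in infected tissue are not printed, since they may come from the fungus. The alternatives tried were DESeq2, RLE size factors, RPM of all reads without TMM, no filter on low counts, the replicate number as a block, each library left out in turn, thinning to the smallest library, and other limits on read matching and length. Alternatives chosen after the data were seen were limiting each library to its 65535 most abundant sequences, setting sequences missing from mock 1 to 4 reads, removing a linear GC trend per library, and leaving out single-base variants of sequences at least 50 times as abundant. The 2 mock libraries and the 2 infected libraries differed from each other far beyond sampling noise (chi-square per degree of freedom over known miRNAs 451 and 404), so none was treated as a duplicate.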

Results

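Small RNA profiles were obtained from mock-inoculated and Alternaria-infected leaves of tomato cultivar Pusa Ruby, about 72 h after inoculation, to find the microRNAs (miRNAs) that respond to the fungus. Alternaria is a genus of fungi that cause leaf blight. Each group had 2 libraries, and the listed reads ranged from 1509619 in infected 2 to 5092406 in mock 2. Together the libraries held 1727371 unique sequences, of which 77585 had at least 10 reads. Over the known miRNAs, the Spearman correlation across miRNAs, which are not independent replicates, was 0.96 between mock 1 and mock 2 and 0.77 between infected 1 and infected 2. Between the groups it was 0.92 for infected 1 with mock 1 and 0.89 with mock 2. For infected 2 it was 0.76 with mock 1 and 0.83 with mock 2. Infected 1 was thus closer to both mock libraries than to infected 2.

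The fungus was measured directly in the libraries through fragments of its ribosomal RNA (rRNA). Infected leaves held 3518 ± 900 (SD, n = 2) such reads per 1000000 reads (RPM), with 4154 in infected 1 and 2882 in infected 2, against 4.40 ± 1.51 (SD, n = 2) in mock leaves. The ratio of the means was 799. It has no firm value with matches of at least 21 nt, where mock 1 had 0 listed reads, or with each library limited to as many of its most abundant sequences as mock 1 lists, where mock 2 had 0. The fragments covered all 157 nt of the fungal rRNA sequence searched in both infected libraries. The mock values rested on 14 reads in mock 1, from 2 sequences that cover 19 nt, and 17 in mock 2. Fragments of the matching plant rRNA stood at 9847 ± 113 (SD, n = 2) RPM in mock and 12919 ± 7946 (SD, n = 2) in infected leaves. Relative to 100 such plant reads there were 56.9 fungal reads in infected 1 and 15.5 in infected 2. The plant sequence searched was 127 nt long and the fungal one 157 nt. These ratios are therefore not like for like between the organisms and serve only to compare libraries. The exact permutation p of the fungal difference was 0.333, the smallest that 2 against 2 libraries allow.

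The length classes of all listed reads, which were not mapped to the plant and include fungal and rRNA fragments, were compared next. Reads of 21 nt, the length of most miRNAs, made up 23.5% ± 5.17 (SD, n = 2) of the reads in infected and 17.9% ± 1.49 (SD, n = 2) in mock leaves. Reads of 24 nt, the length of the small interfering RNAs that direct DNA methylation at repeats, made up 14.5% ± 0.976 (SD, n = 2) of the reads in infected and 20.02% ± 6.01 (SD, n = 2) in mock leaves. The differences, 5.60 and -5.53 percentage points, were about as large as the SD of the more variable group. With each library limited to as many of its most abundant sequences as mock 1 lists, 24 nt reads made up 15.8% ± 0.065 (SD, n = 2) in mock and 10.8% ± 1.56 (SD, n = 2) in infected leaves, a difference of -5.04 points. Infected 2 stood apart in other measures of its reads. A was the first base of 32.7% of its 24 nt reads, against 61.1% in mock 1, 59.7% in mock 2 and 53.3% in infected 1, and 25 nt reads made up 13.6% of it, against 6.24%, 6.53% and 7.25%. Counted as unique sequences, the 24 nt class held 32.4% ± 7.84 (SD, n = 2) in infected and 45.1% ± 0.532 (SD, n = 2) in mock leaves, and the 22 nt class 11.3% in both groups (difference -0.0126 points, exact permutation p = 1). The 22 nt class took 15.9% ± 4.23 (SD, n = 2) of the infected and 26.03% ± 6.29 (SD, n = 2) of the mock reads. The exact permutation p of each of the other differences was 0.333, the smallest possible. Without infected 1 the 21 nt difference was 1.95 percentage points in place of 5.60, and without mock 2 the 24 nt difference was -1.28 points in place of -5.53.

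**Figure D1:**
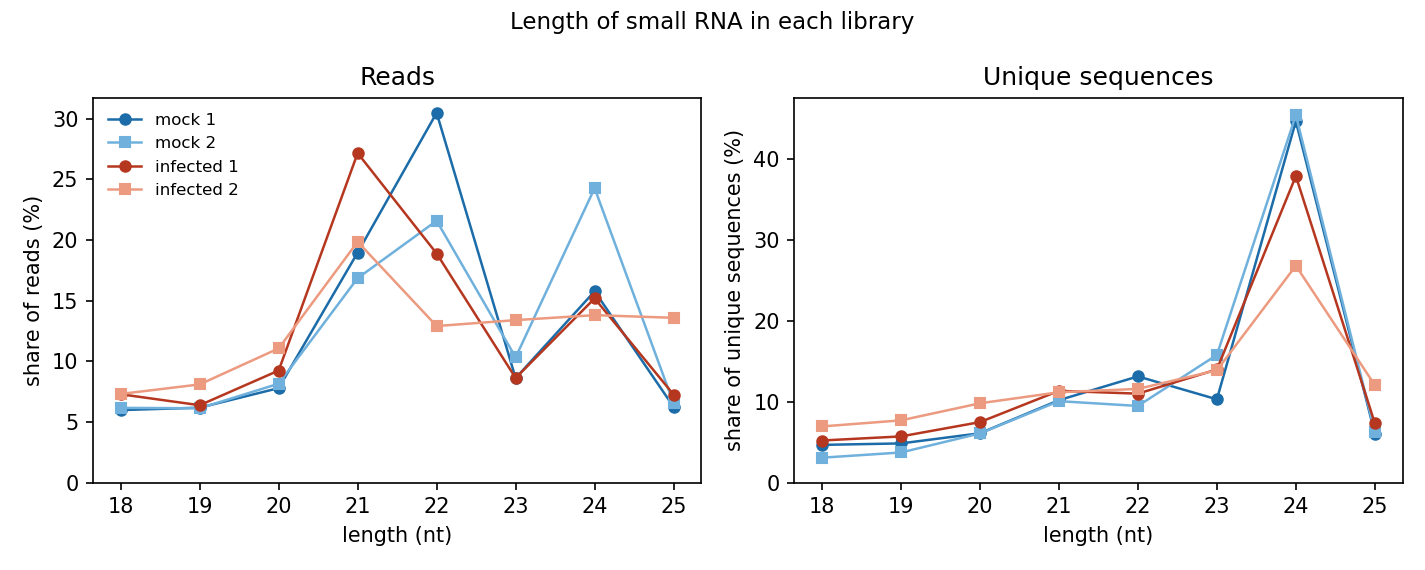
Share of reads (left) and of unique sequences (right) by length in nt, one line per library. In mock 1 and mock 2 the 22 nt class held 30.5% and 21.6% of the reads, and in infected 1 and infected 2 it held 18.9% and 12.9%.

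A single sequence outside the known miRNAs accounted for the whole difference in the 21 nt class and another for that in the 22 nt class. The 22 nt sequence AGTTACTAATTCATGATCTGGC alone made up 19.6% of the reads of mock 1 and 10.8% of mock 2, against 8.24% of infected 1 and 1.06% of infected 2. The 21 nt sequence CCCAGTCCCGAACCCGTCGGC made up 1.91% of mock 1 and 1.64% of mock 2, against 13.04% of infected 1 and 5.47% of infected 2. Each had an exact permutation p of 0.333. Without the first, the 22 nt class held 10.8% ± 0.0997 (SD, n = 2) of the mock and 11.2% ± 0.846 (SD, n = 2) of the infected reads. Without the second, the 21 nt class held 16.1% ± 1.30 (SD, n = 2) of the mock and 14.2% ± 0.183 (SD, n = 2) of the infected reads, so its direction turned. Without its most read sequence the 24 nt class had a difference of -5.35 points with an exact permutation p of 0.667, and mock 1 held 15.01% and infected 1 15.02%. Neither belongs to the 46 reference entries, both were chosen after their values were seen, and their loci were not analysed here. Fragments of the chloroplast 4.5S ribosomal RNA took 11.0% ± 2.90 (SD, n = 2) of the mock and 6.77% ± 6.12 (SD, n = 2) of the infected reads, with 13.01% in mock 1, 8.92% in mock 2, 2.44% in infected 1 and 11.1% in infected 2, so infected 2 lay between the mock libraries. Between 75.3% and 83.3% of these reads ended at the 3' end of the molecule. Known miRNAs took 3.68% ± 0.0028 (SD, n = 2) of the infected and 5.69% ± 1.68 (SD, n = 2) of the mock reads, a difference with an exact permutation p of 0.333. Without mock 1 that difference was -0.83 percentage points in place of -2.02, and without mock 2 it was -3.20.

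Which known miRNAs differed with infection was tested for the 31 of 46 entries with enough reads. One passed. miR397, which targets laccase transcripts and accumulates when copper is scarce, was lower in infected leaves. It had 148 RPM in mock 1 and 95.4 in mock 2, against 3.55 in infected 1 and 3.31 in infected 2. Its log2 fold change was -3.74 (SE 1.09, edgeR quasi-likelihood adjusted p = 0.0342), and its most read form was ATTGAGTGCAGCGTTGATGAC. No known miRNA passed as higher (0 of 31), and 2 of 31 had an unadjusted p under 0.05. DESeq2 also called miR397 lower and 0 miRNAs higher. The call was lost when any of the libraries was left out, with edgeR adjusted p of 0.42 without mock 1, 0.122 without mock 2, 0.0795 without infected 1 and 0.119 without infected 2, while the log2 fold change lay between -4.70 and -3.09. Without infected 2 the Trizol libraries alone remain, with 1 infected library, and the log2 fold change of miR397 was -4.70.

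The copper list holds miR397, miR398 and miR408, which are induced by copper shortage and repress copper proteins. Camera placed the list lower in infected leaves relative to the other miRNAs (adjusted p = 0.0305 over 5 lists tested with limma), but not with an estimated correlation (adjusted p = 0.531). With an estimated correlation the list was not called in any alternative either. One member of 3 passed the test, both over all miRNAs and adjusted over the list alone. miR398, which targets copper/zinc superoxide dismutases, stood at 6391 and 2236 RPM in mock 1 and mock 2 and at 479 and 1451 in infected 1 and infected 2, and its log2 fold change was -0.19 (SE 1.19, edgeR adjusted p = 0.909) with TMM and -2.16 (SE 1.34, adjusted p = 0.62) by RPM scaling. miR408, which targets plantacyanin and laccase transcripts, stood at 248 and 227 in the mock libraries, 29.6 in infected 1 and 371 in infected 2. Its log2 fold change was 1.71 (SE 1.19, edgeR adjusted p = 0.794) with TMM and -0.25 by RPM scaling. The 2 infected libraries thus lay on opposite sides of the mock libraries for miR408. The list's adjusted p was 0.999 without infected 1, 2.0e-04 without infected 2, 0.0815 without mock 1, 0.0673 without mock 2 and 0.0684 with RPM scaling.

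For most of the other miRNAs the direction depended on the scaling. TMM scales to the known miRNAs, and its factor was 0.468 in infected 2 against 1.22 to 1.38 in the other libraries. With TMM the median log2 fold change of the 31 miRNAs was 0.28, with 10 below 0. With scaling to RPM over all reads it was -0.65, with 28 below 0, and the median shift between the scalings was -1.22. The mean GC content of the reads was 46.8% in mock 1, 45.5% in mock 2, 54.0% in infected 1 and 56.6% in infected 2, so it was higher in both infected libraries. Over unique sequences it was 44.9% in mock 1, whose list is incomplete, 40.1% in mock 2, 42.7% in infected 1 and 50.4% in infected 2. By that measure infected 1 lay between the mock libraries. Over the 13 tested miRNAs with a GC content below 50%, infected 2 held a median of 0.248 times the RPM of infected 1, and over the 12 with at least 55% it held 1.16 times.

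The silencing list holds miR168, miR162 and miR403, which target transcripts of the silencing proteins ARGONAUTE and DICER-LIKE. None of the 3 passed (adjusted over the list alone, 0), and camera gave an adjusted p of 0.406. Fry with TMM, which tests whether the members of a list move one way, gave this list the lowest adjusted p of the 5, 0.109. With TMM all 3 members had a log2 fold change above 0 (median 1.01), and with RPM scaling 1 of the 3 did (median -0.43). miR168, which targets ARGONAUTE transcripts, had 1958 and 984 RPM in the mock libraries and 2372 and 2787 in the infected ones, with a log2 fold change of 2.46 (SE 1.25, edgeR adjusted p = 0.54) and 0.81 by RPM scaling. Its most read form was the 22 nt TCGCTTGGTGCAGGTCGGGACC, with 67.2% to 79.1% of the reads of the 22 and 21 nt forms across libraries. miR162, which targets DICER-LIKE transcripts, had 709 ± 463 (SD, n = 2) RPM in mock and 526 ± 226 (SD, n = 2) in infected leaves. miR403 had 422, 243 and 406 in mock 1, mock 2 and infected 1, and 27.8 in infected 2.

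The immune receptor list holds miRNAs assigned from general knowledge to transcripts of immune receptors. Among them is the miR482 family, which targets transcripts of nucleotide-binding leucine-rich repeat (NLR) receptors. None of its 9 tested members passed (adjusted over the list alone, 0). With TMM 8 of the 9 had a log2 fold change above 0 (camera adjusted p = 0.212), and with RPM scaling 1 of the 9 did (camera adjusted p = 0.12). miR482b (TCTTGCCTACACCGCCCATGCC) had 1549 and 512 RPM in the mock libraries and 1629 and 2305 in the infected ones, with a log2 fold change of 2.72 (SE 1.27, edgeR adjusted p = 0.54) and 0.93 by RPM scaling. miR482c had 77.9 ± 14.6 (SD, n = 2) RPM in mock and 55.01 ± 30.9 (SD, n = 2) in infected leaves. miR6027 and miR6024 were spread widely between the infected libraries. miR6027 had 388 in infected 1 and 65.6 in infected 2, and miR6024 had 105 and 7.95, against 393 ± 228 and 176 ± 72.2 (SD, n = 2) in mock leaves. Without mock 2, miR6022 of this list was called higher (log2 fold change 1.86), in a fit that leaves 1 mock library. Mock 2 held the most of its reads, with 41, against 5 listed in mock 1, 18 in infected 1 and 2 in infected 2. In RPM infected 2 lay below mock 1 (1.32 against 1.95). With the GC trend of each library removed, the list itself was called by camera (adjusted p = 0.0195, and adjusted p = 0.406 with an estimated correlation).

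**Figure D2:**
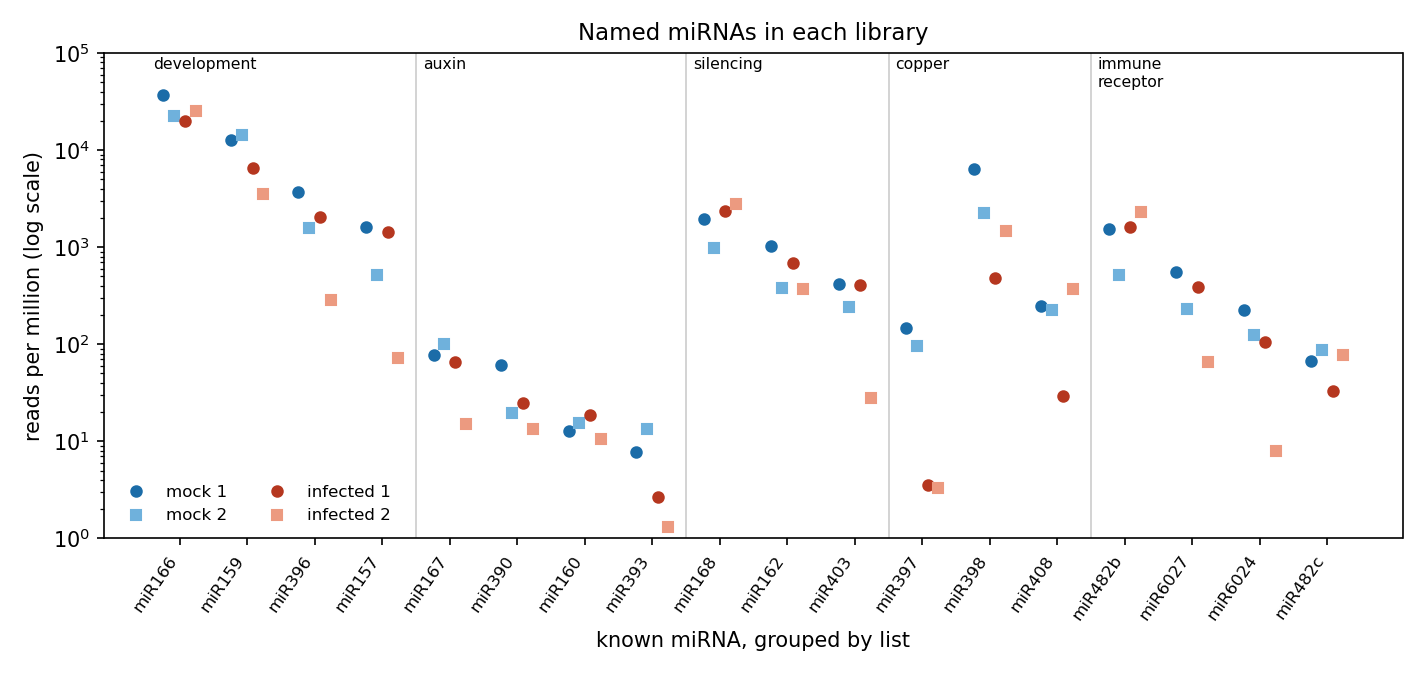
RPM (log scale) of the 18 named miRNAs with enough reads to be tested, one point per library, grouped by list. miR397 was at 3.55 and 3.31 in infected 1 and infected 2 against 148 and 95.4 in the mock libraries, whereas the infected libraries of miR408 were at 29.6 and 371.

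The development list held miR166 and miR159, the 2 most abundant miRNAs, and none of its 9 tested members passed (camera adjusted p = 0.776, adjusted over the list alone 0). miR166, counted together with miR165, which targets transcripts of class III homeodomain-leucine zipper factors, had 29735 ± 10095 (SD, n = 2) RPM in mock and 22422 ± 3651 (SD, n = 2) in infected leaves. miR159, which targets GAMYB-like transcripts, had 13459 ± 1107 (SD, n = 2) in mock and 5024 ± 2067 (SD, n = 2) in infected leaves. Its log2 fold change was -0.18 (SE 1.11, edgeR adjusted p = 0.909) with TMM and -1.42 by RPM scaling. miR396, which targets growth-regulating factors, had 3739 and 1589 in the mock libraries and 2041 and 282 in the infected ones. miR157, which targets SPL transcription factors, had 1610 and 512 in the mock libraries and 1431 and 72.2 in the infected ones. The auxin list (miR167, miR390, miR160 and miR393, which act on auxin response factors and receptors) had 0 of 4 tested members past the threshold (camera adjusted p = 0.833, adjusted over the list alone 0). miR167 had 89.5 ± 17.2 (SD, n = 2) RPM in mock and 40.3 ± 35.5 (SD, n = 2) in infected leaves, miR390 had 40.3 ± 29.2 and 19.1 ± 8.22, miR160 had 14.1 ± 1.71 and 14.6 ± 5.70, and miR393 had 10.6 ± 3.92 and 2.00 ± 0.948. For both lists the median and the mean log2 fold change were above 0 while camera placed them lower relative to the other miRNAs. The nutrient list had too few reads to pass the filter. Without the filter 5 of its members were tested, with a median log2 fold change of -1.18 and a camera adjusted p of 0.788. Its most read members, miR395 and miR169d, had 2.64 ± 0.683 and 2.15 ± 0.269 (SD, n = 2) RPM in mock and 0.662 ± 0.937 and 0.627 ± 0.0495 (SD, n = 2) in infected leaves. miR399 and miR827 had at most 0.592 RPM of listed reads in any library. In mock 1 they had 0 listed reads, where a sequence can have up to 4 reads that are not listed.

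Unique sequences were then compared without any list of miRNAs. Of the 27148 tested, edgeR called 0 higher and 0 lower (smallest adjusted p = 0.143). At an unadjusted p under 0.05 there were 3794 sequences, 2763 higher and 1031 lower. With RPM of all reads edgeR called 1534 higher and 293 lower. DESeq2 called 1897 higher and 126 lower, and 72.5% of those higher had 0 listed reads in both mock libraries. In RPM, both infected libraries lay above both mock libraries for 18.7% of the tested sequences and below them for 35.6%. Among 4 libraries that differ by chance alone, each direction would have 16.7%. These libraries differ in depth, mock 1 lists no sequence with fewer than 4 reads, and the sequences are not independent. The shares are therefore not a measure of excess over chance. Within the Trizol libraries, that is without infected 2, edgeR called 6192 higher and 1055 lower, and without infected 1 it called 3800 higher and 9618 lower. In these fits the lone infected library is assumed to vary like the mock libraries.

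The 5 sequences with the smallest p in the higher direction, none of which passed, had 37.0 to 109 RPM in infected 1 and 84.8 to 125 in infected 2. They had at most 1 read in mock 2 and 0 listed reads in mock 1, where up to 4 reads can be missing. Their lengths were 19, 21, 18, 25 and 23 nt. In the lower direction, TAACAGACCGGTCGACTTGAAC had 70.7 and 43.6 RPM in mock 1 and mock 2 and 0 reads in both infected libraries, at least 30.3-fold lower than mock 2 against a floor of 3 reads per infected library. ACAGACCGGTAGCCTTGAAC had 50.8 and 39.5 and again 0 reads, at least 27.4-fold lower than mock 2. Each differs by a single base (A13C, counted from 1 at the 5' end of the read) from a fragment of the chloroplast 4.5S ribosomal RNA, and in mock 2 the fragments had 53623 and 61302 reads where the variants had 222 and 201. GTGCTGTGATGATAAATGCACAATT had 32.03 and 24.0 RPM and 0 reads, at least 16.7-fold lower than mock 2, and GTGCTGTGATGATTAATGTGCAATT had 34.4 and 58.3 against 0.296 and 1.32. TCAACGCTAAACTCGATCATG had 73.4 and 75.6 against 1.78 and 1.32, with a log2 fold change of -5.20 (SE 0.95, edgeR adjusted p = 0.143). None of the 5 passed with edgeR, and DESeq2 gave adjusted p of 3.5e-05 to 3.9e-04 for them.

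The variant bases were followed by their position in the read. In 36 abundant sequences with A at read position 13, other than the 22 nt sequence above and the chloroplast fragments, C was read in place of A in 36.0 of 10000 reads in mock 1, 44.5 in mock 2, 0.776 in infected 1 and 0.50 in infected 2. Pooled over the 20 other read positions the rate was between 0.0677 and 0.954 per 10000 in the 4 libraries. At position 12 the infected libraries were higher, with A-to-C at 1.40 and 1.31 in mock 1 and mock 2 and 3.83 and 4.51 in infected 1 and infected 2, and A-to-T at 0, 0.0654, 3.41 and 3.56. The A-to-C rate was higher in infected 1 than in mock 2 in 16 of 38 sequences and the reverse in 2, and 172 of the 213 variant reads of infected 1 came from 1 sequence. C-to-T at position 12 stood at 0.522, 0.748, 3.77 and 5.09. Its rate was higher in infected 1 than in mock 2 in 27 of 68 sequences and the reverse in 5. Of its 72 variant reads in infected 1, 29 came from 1 sequence. T-to-G at position 13 stood at 2.61, 3.58, 0.0666 and 0. In mock 1, where sequences with fewer than 4 reads are not listed, these rates are lower bounds.

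**Figure D3:**
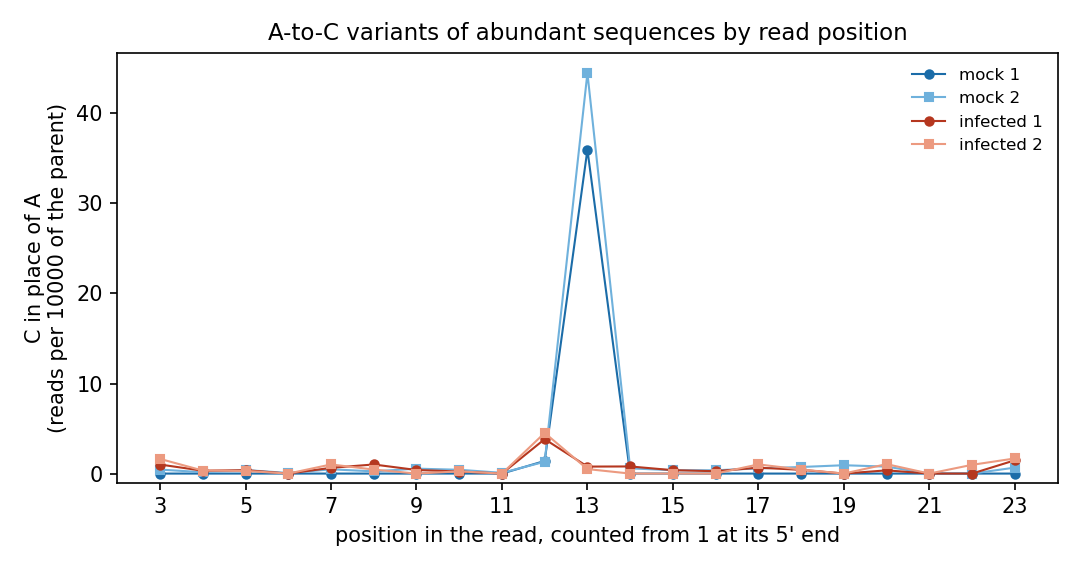
Reads with C in place of A per 10000 reads of the parent sequence (y axis) by position in the read (x axis), one line per library. Mock 1 and mock 2 reached 36.0 and 44.5 at position 13, where infected 1 and infected 2 were at 0.776 and 0.50.

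The ratio of RPM between the libraries of a group was compared with GC content across the tested miRNAs, which are not independent replicates. Spearman's rho was 0.48 for infected 2 over infected 1 and -0.078 for mock 2 over mock 1 (31 miRNAs each).

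**Figure D4:**
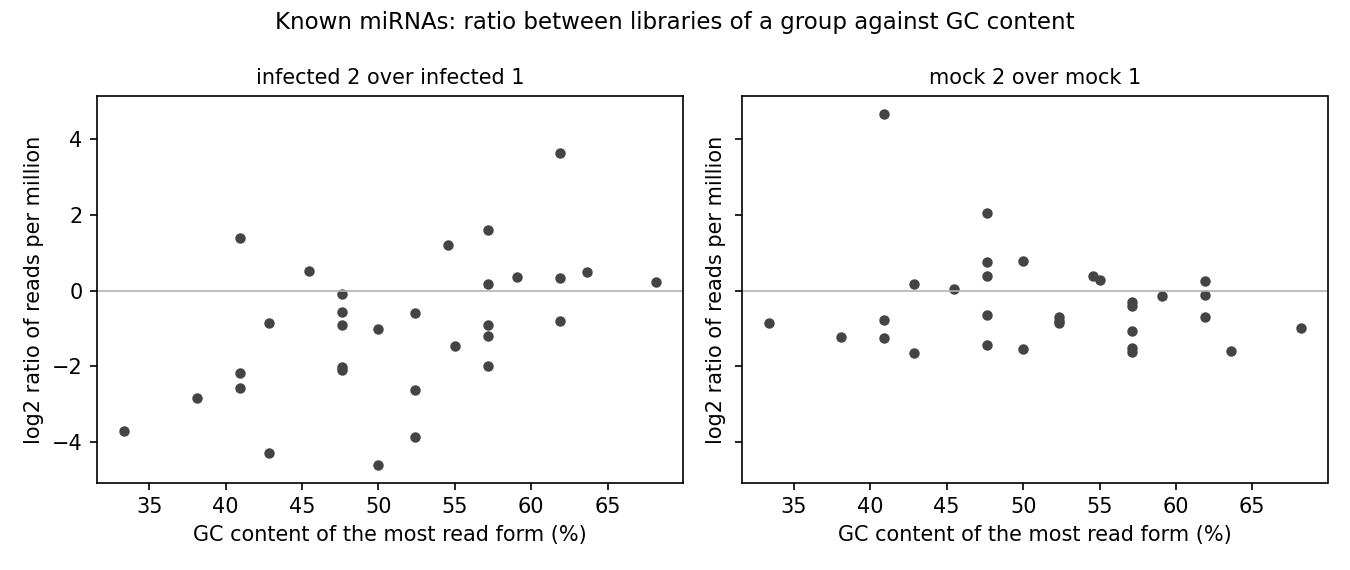
Log2 ratio of RPM of infected 2 to infected 1 (left) and of mock 2 to mock 1 (right) against the GC content in % of the most read form, one point per tested miRNA. The left ratios ran from -4.61 to 3.65 with a rho of 0.48, and the right ones from -1.65 to 4.67 with a rho of -0.078.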

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

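A signal was present in the infected libraries that the comparisons of known miRNAs do not use. It consists of 357 unique sequences with at least 10 RPM in both infected libraries and at most 4 reads in each mock library. They took 2.55% of the reads of infected 1 and 1.29% of infected 2. With all libraries thinned to 1509619 reads, 440 sequences met these limits. The limit of 4 reads stayed the same while the mock libraries lost reads, so absence became easier. The 440 are a new selection, and the count does not test whether the 357 depend on depth. Of the 357, 20 match the fungal rRNA, 0 match a known miRNA, and 37.8% are 21, 22 or 24 nt long, against 41.2% of the 3363 sequences present at that level in all 4 libraries. The opposite set, present in both mock libraries and nearly absent from the infected ones, had 64 sequences, 212 after the same thinning, and of the 64, 59.4% are 21, 22 or 24 nt long.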

How the results depend on the processing

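The settings chosen after the data were seen are the limit of each library to as many of its most abundant sequences as mock 1 lists, the filling of mock 1 with 4 reads, the GC correction, the removal of single-base variants and the removal of the most read sequence of a length class. The denominator of all reads gave no separate value, since the files hold 18 to 25 nt reads alone. The replicate numbers are not known to pair libraries (correlation of same-numbered deviations 0.32 for known miRNAs and -0.011 for unique sequences). With the replicate block, 0 known miRNAs were lower in place of 1 (miR397 adjusted p = 0.0665), and 1203 unique sequences were higher and 68 lower in place of 0 and 0. It changed no call of a list. DESeq2 called 1897 unique sequences higher and 126 lower, and RPM of all reads called 1534 and 293. Leaving out each library gave 0 to 6192 unique sequences higher and 0 to 9618 lower. It gave 0 to 1 known miRNAs higher, 0 lower in each case, and 0 to 1 lists. The lists called numbered 0 with RPM of all reads and 2 with the GC trend removed, in place of 1. With an estimated correlation camera called 0 lists in every setting (lowest adjusted p = 0.406, with the GC trend removed). In every other alternative run, miR397 stayed the only known miRNA called, and edgeR called 0 unique sequences. The 10 named unique sequences kept their direction in all 133 alternatives that gave a value (0 turned), and passed in 50. The share difference of 21 nt was 1.13 points and that of 24 nt -12.7 points when unique sequences were counted. Without the most read sequence of the class the 21 nt difference turned, to -1.89 points. The fungal rRNA difference was 2788 RPM with matches of at least 21 nt, in place of 3514. Except for that sequence, the cause was not tested for any of these.

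Of the 18 named miRNAs tested, 6 kept the sign of their log2 fold change in every alternative that gave a value (miR397, miR160, miR393, miR168, miR482b and miR6024). For miR393 thinning gave no value. Of the 251 values of all 18, 49 turned. None of those turns involved a call, and their cause was not tested. With RPM of all reads the values were -0.41 for miR166, -0.50 for miR157, -1.07 for miR390, -0.43 for miR162, -0.61 for miR403, -0.25 for miR408, -0.79 for miR6027 and -0.51 for miR482c. With DESeq2, and likewise with RLE factors, they were -0.070 for miR157, -0.11 for miR390, -0.19 for miR403 and -0.18 for miR6027. With the replicate block they were -0.14 for miR157 and -0.22 for miR403. Thinning gave -0.024 for miR157, -0.13 for miR390, -0.24 for miR403 and -0.23 for miR6027. Identical reads gave -0.086 for miR390, -0.093 for miR403 and -0.090 for miR6027, and 1 mismatch gave -0.053, -0.092 and -0.085. The limit to the most abundant sequences gave -0.13 for miR403 and -0.0028 for miR6027. The GC correction gave 0.49 for miR159 and 0.36 for miR396. Leaving out each library gave ranges of -0.19 to 1.86 for miR166, -0.77 to 0.078 for miR159, -1.06 to 0.082 for miR396, -1.65 to 0.95 for miR157, -0.94 to 0.11 for miR167, -0.43 to 0.68 for miR390, -1.45 to 0.70 for miR403, -2.67 to 0.64 for miR398, -2.68 to 2.68 for miR408, -0.40 to 0.45 for miR6027 and -0.98 to 1.95 for miR482c. Of the 46 entries, 15 had too few reads to be tested. Some, among them miR169a and miR858, had 0 listed reads in every library. Whether depth or the reference sequences limit these entries was not tested.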

Other observations

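Of the tests below, those of the ratio between the infected libraries, those of single-base variants (except a first test of an RNA variant, which was replaced) and the scaling test of miR397 were chosen after the result was seen.

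Both mock libraries carried A-to-C variants mainly at read position 13. In 36 abundant sequences with A at position 13, counted from the 5' end, C was read there in 36.0 of 10000 reads in mock 1 and 44.5 in mock 2, against 0.776 in infected 1 and 0.50 in infected 2. In all 36 the rate was higher in mock 2 than in infected 1, a ratio of 57.3 over sequences other than those on which the pattern was first seen. Length forms of one RNA were not merged, so the 36 are not independent of each other or of the sequences left out. An error spread over every read position is argued against by a ratio of 0.422 at the other positions (0.978 without position 12), and an RNA variant of the plant by chloroplast 4.5S rRNA, whose same 3 A bases gave 52.9 times the rate when they fell at read position 13 (36.3 against 0.687 per 10000 in mock 2). This rRNA was among the sequences on which the pattern was first seen. Earlier tests of this pattern were replaced once its place in the read was seen. The first, of a run-wide error over all positions, came out against that error (lowest ratio of a sequence, 0). The second, written before its result was seen, came out in favour of an RNA variant, with 1 of 18 A positions (5.56%) at least 5 times as high in both mock libraries, but a fault at one read position gives the same outcome, so it did not separate these explanations. The infected libraries had a smaller excess of their own at position 12. A-to-T was at 3.41 and 3.56 per 10000 against 0 and 0.0654 in mock 1 and mock 2, 140 of the 190 variant reads of infected 1 coming from 1 sequence. Every other substitution at position 12 was also higher in both infected libraries than in both mock libraries. C-to-T was at 3.77 and 5.09 against 0.522 and 0.748, with 29 of the 72 variant reads of infected 1 from 1 sequence. What stays open, as a hypothesis, is a base-calling fault at cycle 13 in a sequencing run that the mock libraries may share and the infected ones do not, in which case sequencing run and infection cannot be separated in any comparison here. Such variants were 8 of the 1031 unique sequences lower at an unadjusted p under 0.05 and 0 of the 2763 higher, and 2 of the 5 named lower sequences are among them.

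Infected 2 held 21 of the 31 tested miRNAs at lower RPM than infected 1. Mock 2 did so relative to mock 1 for 21 of 31 as well, with a narrower spread. The RPM values of mock 1 are too high, since its list is incomplete, and this alone lowers mock 2 relative to mock 1. The count for the mock libraries is therefore not a baseline for the infected ones. A larger share of pathogen is argued against by the fungal over plant rRNA ratio, which in infected 2 was 0.273 times that in infected 1. Dilution of all miRNAs by other RNA stays open. The SD of the log2 ratio was 1.86 over miRNAs and 1.27 between the mock libraries. By the limit set for this test the first value counts against dilution, but the mock libraries passed that limit too. The mock SD includes miR482a and miR6022 (log2 ratios 4.67 and 2.04), which had 8 and 5 listed reads in the incomplete mock 1. It may therefore overstate the usual spread, and the SD does not decide on a common factor. The known miRNAs together took 3.68% of infected 1 and 3.67% of infected 2, which argues against a common fall, but this sum rests mostly on miR166 (19840 and 25003 RPM), a single miRNA within that spread. The log2 ratio followed GC content across the miRNAs, which are not independent replicates, with a Spearman rho of 0.48, against -0.078 for the mock libraries. Over 5895 unique sequences rho was 0.22, below the 0.29 between infected 1 and mock 2. GC-dependent recovery in infected 2 may therefore account for part of the pattern. The extraction kit, which differed for this library alone, and a difference between the leaves were not tested and cannot be told from each other.

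For miR397 the technical explanations tested left the difference in place. The log2 fold change was -3.51 (SE 1.01) with the GC trend of each library removed and -5.13 (SE 1.14) by RPM of all reads, each more than its SE below -2. Neither GC content nor scaling to the other miRNAs is therefore the whole cause. Without infected 2 the log2 fold change was -4.70, with 1 infected library left, and the call was lost. Infected 1 had 3.55 RPM against 148 and 95.4 in mock 1 and mock 2, so infected 2 alone does not make the difference. Base-calling errors were tested as well, and 0 of the miR397 sequences were 1 substitution away from a sequence at least 50 times as abundant. The infection and the sampling of the infection zone alone remain open and are confounded with the groups. Other differences between sequencing runs remain open as well, if the groups were sequenced in separate runs, which the labels do not say.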
